A study of Mus musculus with 24 samples.

How the data were processed

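Total RNA from mouse pancreas was labelled with biotin and hybridised to Illumina single-colour bead arrays, per the labels. The deposited table of non-normalized values gave, per the file headers, an average bead signal and a detection p-value for each of 45281 probes on each of 24 arrays. The deposited signal is a linear intensity, and its values were neither background-subtracted nor normalized between arrays. The deposited detection p-value moved in steps that imply 936 negative control probes. A further deposited table held log2 values, and R 3.1.2 and limma 3.22.1 were used, per the submitters' processing notes. The scale and centring of those deposited log2 values were found by comparison with the signals: they matched the normalization used here, with the 99th percentile of the absolute difference at 0.00194 and the largest at 0.104, and every array had a median of 4.37 to the printed digits. The scanner software, its settings and the array chip that held each sample were not given in the sources used here.

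Signals were background-corrected and quantile normalized with neqc of limma 3.58.1 in R 4.3.3, with the background inferred from the detection p-values and an offset of 16, and taken to log2. Probes with a detection p under 0.05 on at least 4 of the 24 arrays were kept, which left 15328. The platform annotation gave 1 gene symbol to 13086 kept probes, several to 8 and none to 2234, and the named probes covered 9164 genes. Probes with several symbols or none stayed in the tests and were not named. No genome positions are given, since the build behind the array annotation is not given in the sources used here.

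Median signal per array was 81.3 to 98.7, the 95th percentile 203.3 to 313.7, and 24.1% to 31.1% of probes were detected. The number of arrays, 4 per group, limits the precision. A probe not detected on any array of a group has only a bound there. Its fold was computed from the brighter group's mean and, for the dimmer group, from the higher of the lowest signal among detected probes and the probe's own value on each array, and is written as at least that fold.

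The groups were taken from the sample titles. All 24 arrays entered a single limma fit with group means and no covariate, moderated with eBayes, so that the groups share an estimate of the spread. Each treated group was compared with water. Further contrasts were the mean of the 4 berry groups against water, AFFB against PAE 1X, a linear trend over water, 0.1X, 1X and 3X with scores 0 to 3, and a moderated F test over all 5 treatments. A probe passed at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, and tests were two-sided. Errors of log2 differences are standard errors of that fit.

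Gene lists for cell types and pathways were written before the data were examined, as were the tests and the alternatives, apart from those that the closing section names as chosen afterwards. Of 39 lists, 34 had at least 5 kept genes and were tested with fry of limma, which asks whether a list's genes move on balance one way, and its values were adjusted over the 34 lists of a comparison. Each gene entered by its kept probe of highest mean. Camera with a preset correlation of 0.01 and with an estimated correlation, and fry for change in either direction, were alternatives.

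Named genes followed a rule fixed in the same way. Among passing probes with 1 symbol, the 12 largest rises and 12 largest falls were named, provided that all arrays of a treated group lay on the same side of the water mean (no such condition for the trend, the F test and the berry mean). Where fewer than 10 probes passed, the 10 smallest p were given as well. From a list that passed, up to 4 members with the smallest p were named, and a panel of 20 genes was followed throughout. Members of lists that did not pass, such as Alas2, Mcm6, Gapdh, Pgam1, Ehhadh, H2-Aa and Acot2, were chosen after their values were seen.

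Alternatives changed the background correction, the normalization, the probe filter, the variance model, the arrays in the fit, the dose scale, the set test or the probe per gene, added a replicate block or covariates, used the deposited log2 values, or left out each array in turn. The composition covariates were the array means of the adipocyte list (11 kept genes) and of the B and plasma cell list (4 kept genes, too few to be tested itself).

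The fit was tested on simulated data with the spread of these arrays, in 10 simulations with 200 changed probes among 15328. For PAE 3X against water, 17.2% of changes of 0.5 log2 units were recovered, 85.5% of changes of 1 and 98.3% of changes of 2. For sitagliptin the shares were 15.5%, 83.9% and 98.9%, and for the trend, with the change reached over its 3 steps, 19.3%, 86.1% and 98.6%. With 200 probes changed at once, the adjusted threshold is easier to pass than with few. These shares thus overstate recovery where few probes change. False calls had a median of 3.5 and a highest count of 74 for PAE 3X, and of 3.5 and 18 for the trend. A shift of 0.5 log2 units in 5 lists was recovered in 80% of cases for PAE 0.1X, with 1 false list over 10 simulations. The same limit holds here, since the 5 lists were shifted at once.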

Results

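Gene expression was measured in the pancreas of male C57BL/6J mice, an inbred strain prone to diet-induced obesity, after 12 weeks on a high-fat diet. The 24 single-colour bead arrays formed 6 groups of 4. One group drank water and served as the control. Another received AFFB, a fermented blackberry and blueberry beverage from which the alcohol had been removed. Its anthocyanin dose was 8.4 mg per kg body weight per day. Further groups received PAE, the phenolic extract of that beverage, at anthocyanin doses of 1.1 (0.1X), 9.0 (1X) and 18.9 (3X) mg per kg per day. The highest dose was 3X in the sample titles and 2X in the treatment protocol, and it is called 3X here. At 18.9 against 9.0 mg per kg per day it was nearer to 2X. The last group received sitagliptin, a drug that inhibits the incretin-degrading enzyme DPP-IV, at 150 mg per L of drinking water. The labels do not state outright that each array was a separate mouse, so p-values measure the spread between these samples, which may be technical in part. Each array had a signal for 45281 probes, of which 10888 to 14060 were detected above background, and 15328 probes entered the tests. The number of arrays limits the precision, and the median standard error of a log2 difference from water was 0.17.

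Clock genes and the first principal component separated arrays within groups. The clock score, a summary of 13 circadian clock genes led by the output gene Dbp, was 3.83 in water 4, 4.40 in PAE 1X 4, 4.13 in PAE 3X 2, 4.09 in PAE 3X 3 and 3.96 in sitagliptin 4. The score lay between -2.76 and 0.76 on the other 19 arrays. The first principal component held 28.4% of the variance and placed PAE 1X 2 at 56.1, AFFB 2 at 38.8 and sitagliptin 3 at 33.7, against at most 19.0 on the remaining arrays.

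**Figure D1:**
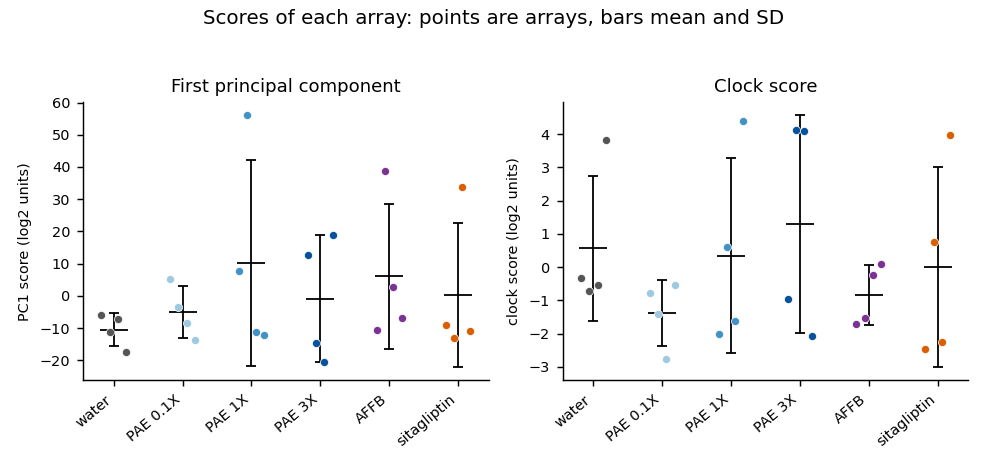
The first principal component score (left) and the clock score (right) of every array, both in log2 units, by group, with a point per array and bars for the mean and SD of 4 arrays. PAE 1X 2 had the highest first component score, 56.1, and 5 arrays in 4 groups had clock scores from 3.83 to 4.40.

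The extract at its highest dose, set against water, asked what the phenolics alone change in the pancreas. Reep6, which encodes a membrane-shaping protein of the endoplasmic reticulum, rose by 2.03 log2 units (SE 0.32), from 6.64 ± 0.42 to 8.66 ± 0.18 (SD, n = 4 each). Slamf9, an immune cell surface receptor, rose by 1.39 (SE 0.25), and Slc7a3, a cationic amino acid transporter, by 0.99 (SE 0.18). Azgp1, a secreted zinc-binding glycoprotein linked to lipid mobilisation, rose by 0.95 (SE 0.18), and Fbp2, the muscle isoform of the gluconeogenic enzyme fructose bisphosphatase, by 0.86 (SE 0.16). Moxd1, a monooxygenase of the dopamine beta-hydroxylase family, was not detected on any of the 4 water arrays and was detected on all 4 PAE 3X arrays, at least 1.63-fold higher. Lpl, the lipase that releases fatty acids from circulating triglycerides, fell by 1.08 (SE 0.19), from 8.58 ± 0.31 to 7.50 ± 0.26.

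These 7 probes, 6 higher and 1 lower, passed in limma at adjusted p from 0.00161 for Moxd1 to 0.0413 for Azgp1 and Fbp2, with each gene on the same side of the water mean on all 4 arrays. Cobl, an actin nucleator, 1.99-fold lower (adjusted p = 0.0512), Lamb3, a laminin chain of basement membranes, at 0.87 (0.0514), and Rprm, a mediator of cell-cycle arrest, at -1.37 (0.0514) did not pass. A second, dimmer Slc7a3 probe differed by -0.23 and a second Azgp1 probe by 0.75, both at adjusted p = 0.999. Adipocyte genes, a list that includes Lpl, were lower for 10 of 11 members (median -0.23, or -0.38 under median scaling), and the list did not pass (adjusted p = 0.419). Median scaling gave 8 higher and 4 lower, and no background correction or the larger offset gave 9 higher and 3 lower. With adipocyte and B cell list means as covariates 2 probes passed, and 0 passed without the 5 arrays of high clock score, while 25, all 7 among them, passed with the clock score as a covariate. Without single arrays the count was 1 (water 2, water 4 or PAE 3X 1), 2 (water 3, PAE 0.1X 2 or PAE 3X 2), 3 (PAE 1X 3), 4 (PAE 3X 3), 14 (AFFB 1 or PAE 1X 2) or 15 (PAE 1X 4). Moxd1 passed in all 24 of these fits, Reep6 in 21, Lpl and Slc7a3 in 16 each, Slamf9 in 15, Fbp2 in 12 and Azgp1 in 9.

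Glycolytic enzymes were lower in PAE 3X for 11 of 11 measured genes, with Gapdh at -0.34 (SE 0.14) and Pgam1 at -0.30 (SE 0.16), and the list did not pass (median -0.16, or -0.06 under median scaling, adjusted p = 0.131). Cell cycle genes were higher for 9 of 11 (median 0.19, or 0.06 under median scaling, adjusted p = 0.131). Adjusted over the list alone, Mcm6 at 0.98 (SE 0.22) and Mcm5 at 0.62 (SE 0.20), subunits of the replicative helicase, rose, and neither passed over all probes. Erythroid genes, markers of blood, had a larger median in the same group (0.84, 3 of 5 higher, adjusted p = 0.466), and Alas2 at 0.98 (SE 0.32) passed over its list alone. The fry test called 0 of 34 lists, with 3 at an unadjusted p under 0.05. Camera called 5 lists with a preset correlation and 0 with an estimated one. Glycolysis passed when only probes detected on all 24 arrays were kept or when no filter was used, and 1 list passed without PAE 3X 4.

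PAE 1X set the extract, at an anthocyanin dose close to that of the beverage, against water. Reep6 rose by 1.94 log2 units (SE 0.32), from 6.64 ± 0.42 to 8.58 ± 0.63 (SD, n = 4 each), and was higher on all 4 arrays. Azgp1 at 1.01 (SE 0.18) and Gcnt1, a glycosyltransferase that branches O-glycans, at -1.42 (SE 0.26) both had adjusted p = 0.0568 and did not pass. Also not passing were Cobl at -1.02, Smim24, a small membrane protein, at -1.34, the alcohol dehydrogenase Adh1 at -0.97, Rprm at -1.28 and Slc7a3 at 0.86. Oxct1, an enzyme of ketone body use, at -0.79 and Cadps2, a factor in dense-core vesicle release, at 0.81 did not pass either. Other probes differed by -1.08 for Gcnt1, -0.86 for Adh1, -1.17 for Oxct1, 0.33 for Azgp1, -0.06 for Cobl and -0.08 for Slc7a3.

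The single PAE 1X call had adjusted p = 0.0390 in limma, and 997 probes had an unadjusted p under 0.05. Over alternatives Reep6 in PAE 1X stayed between 1.40 and 2.16 with adjusted p up to 0.218. No probe passed without water 2, 3 or 4, AFFB 4, PAE 1X 1, 2 or 3, or PAE 3X 1, 2 or 3. Then 2 passed without AFFB 2, PAE 3X 4, sitagliptin 3 or sitagliptin 4, 3 without AFFB 1, 4 without PAE 0.1X 4 or sitagliptin 1, 5 without sitagliptin 2 and 8 without PAE 1X 4. Oxidative phosphorylation genes were lower for 24 of 33 members (median -0.13, adjusted p = 0.334, and a median of 0.03 under median scaling), and ribosomal protein genes for 20 of 31 (median -0.05, adjusted p = 0.390). Fry called 0 lists, with 4 at an unadjusted p under 0.05, and camera called 2 with a preset and 0 with an estimated correlation.

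PAE 0.1X, the lowest dose, had its clearest difference from water in fatty acid oxidation genes and PPAR targets. This list rose, with 12 of 14 measured genes higher and a median of 0.42 log2 units. At the 2 higher doses it did not pass: 7 of 14 were higher in PAE 1X (median 0.01, adjusted p = 0.977) and 9 of 14 in PAE 3X (median 0.10, adjusted p = 0.624). Adjusted over the list alone, 4 genes rose: Acot1, an acyl-CoA thioesterase, by 2.83 (SE 0.61), Angptl4, a secreted inhibitor of lipoprotein lipase, by 2.01 (SE 0.40), Hadhb, a subunit of the mitochondrial trifunctional protein, by 0.65 (SE 0.20), and Acadvl, the very-long-chain acyl-CoA dehydrogenase, by 0.48 (SE 0.15). Each was above the water mean on all 4 arrays. Over all probes 0 of these genes passed. Acot1 went from 5.87 ± 1.07 in water to 8.70 ± 0.85, with 5.82 in PAE 1X and 5.51 in PAE 3X, and Angptl4 from 5.06 ± 0.74 to 7.08 ± 0.58 (SD, n = 4 each). A second Acot1 probe, not detected in water, was at least 2.24-fold higher. The near-identical paralog Acot2 differed by 0.12 (SE 0.17), and which of the paralogs the Acot1 probes read is uncertain.

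The list passed fry at adjusted p = 0.0359 over 34 lists, of which 3 had an unadjusted p under 0.05. Camera gave adjusted p = 7.54e-10 with a preset and 0.0172 with an estimated correlation. Over 42 alternatives the adjusted p of the list ran from 7.54e-10 to 0.171 and was under 0.05 in 23. Without single arrays the call was lost for water 1 (0.136), water 2 (0.0563), water 4 (0.159), PAE 0.1X 1 (0.100), 2 (0.0503), 3 (0.0997) and 4 (0.131), PAE 1X 1 (0.0536), PAE 3X 2 (0.0593) and sitagliptin 1 (0.05). It was also lost without Acot1 and Angptl4 (0.117), without the 5 arrays of high clock score (0.171), with the clock score (0.0893) or adipocyte and B cell list means (0.0517) as covariates, with the replicate block (0.0574), median scaling (0.0796), no filter (0.0738), only the groups compared (0.0954) and fry in either direction (0.0537). Adipocyte genes were lower for 8 of 11 members (adjusted p = 0.810).

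**Figure D2:**
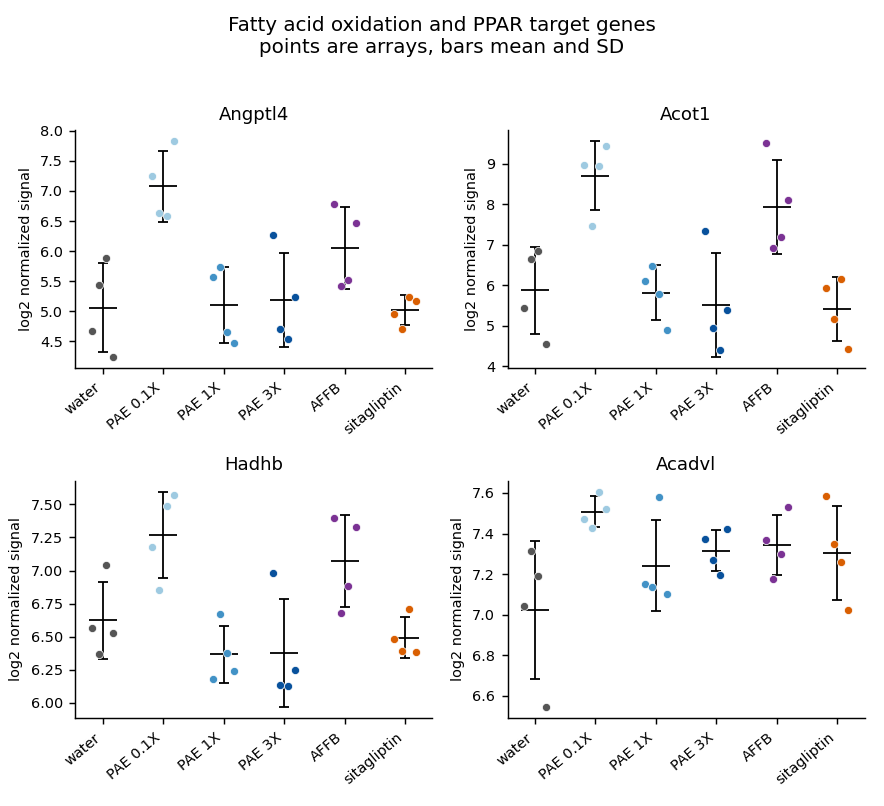
Log2 normalized signal of Angptl4, Acot1, Hadhb and Acadvl on every array, by group, with a point per array and bars for the mean and SD of 4 arrays. Acot1 averaged 8.70 in PAE 0.1X and 7.93 in AFFB against 5.87 in water, and no gene shown passed over all probes in PAE 0.1X or AFFB.

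Among single probes, limma called 0 in PAE 0.1X, with 579 at an unadjusted p under 0.05 and a smallest adjusted p of 0.342, and called 1 without AFFB 1. Besides the genes above, those with the smallest p were Gper1, a membrane estrogen receptor, at -0.92, Slc7a3 at 0.86, Shmt2, the mitochondrial serine hydroxymethyltransferase, at 0.85 and Gm26588 at 0.82. Nr1h4, the bile acid receptor FXR, at 1.25, Cobl at -0.78 and Paf1, a transcription elongation factor, at -0.64 completed them, and none passed. Other probes differed by 0.28 for Acadvl, -0.19 for Slc7a3, 0.05 for Shmt2 and -0.00 for Cobl.

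The trend over water, 0.1X, 1X and 3X, scored 0 to 3, asked which genes had a linear slope over the order of doses. Rises per step were 0.68 log2 units (SE 0.10) for Reep6, 0.48 for Slamf9, 0.37 for Ndrg2 and 0.34 (SE 0.04) for Moxd1. Arhgef25, Lamb3 and Azgp1 rose by 0.32 per step each, Slc7a3 by 0.30, Ptges3l by 0.28, Fbp2 and Igdcc4 by 0.27 and Cd164l2 by 0.26. Per step, Gcnt1 fell by 0.45 (SE 0.08), Rprm fell by 0.44, the stem cell factor receptor Kit fell by 0.38 and Apol7a fell by 0.36. Lpl fell by 0.36 (SE 0.06), Cobl fell by 0.32, Sh3bgrl3 fell by 0.30 and Oxct1 fell by 0.25. Iyd, the deiodinase that recycles iodide from iodotyrosines, fell by 0.24 and fell by 0.23 on its 2 probes.

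**Figure D3:**
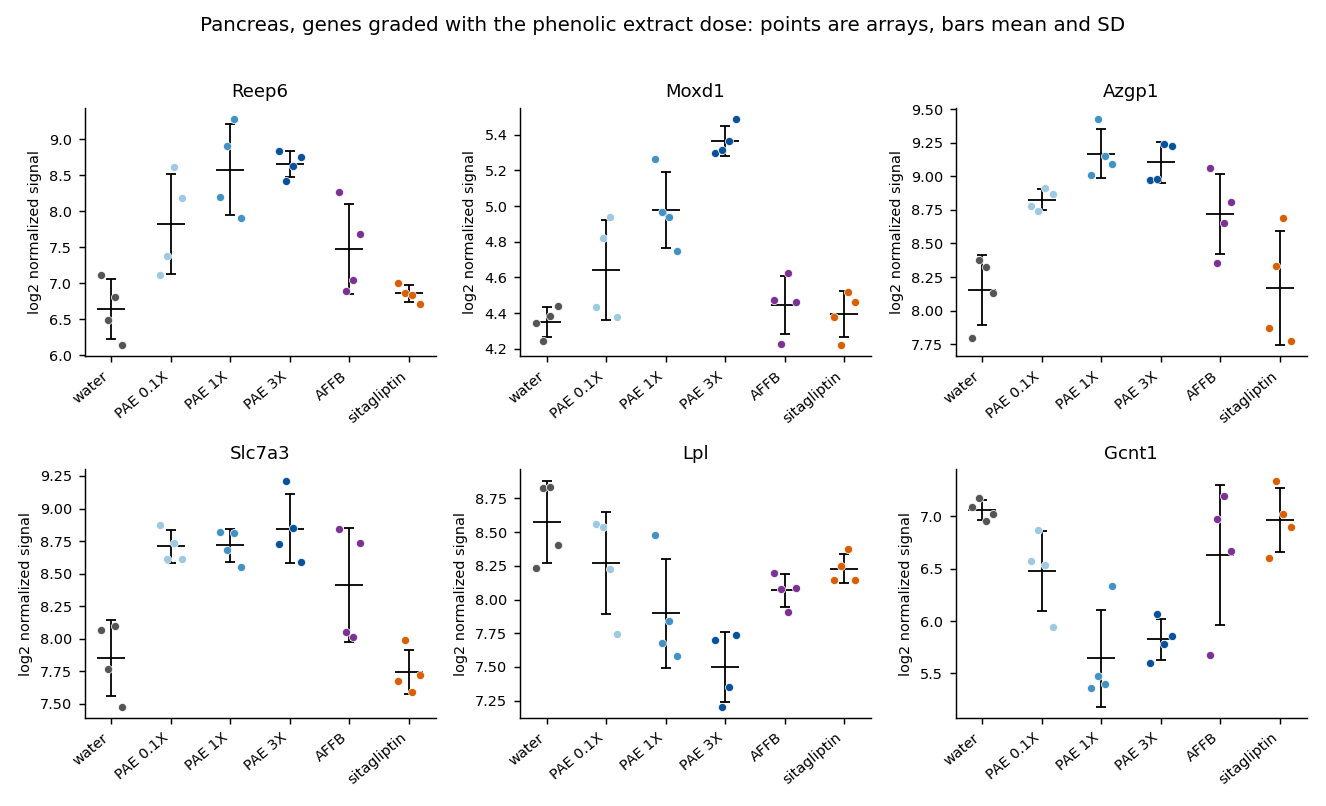
Log2 normalized signal of Reep6, Moxd1, Azgp1, Slc7a3, Lpl and Gcnt1 on every array, by group, with a point per array and bars for the mean and SD of 4 arrays. Reep6 averaged 6.64 in water, 7.82 in PAE 0.1X, 8.58 in PAE 1X and 8.66 in PAE 3X, and Lpl 8.58, 8.27, 7.90 and 7.50.

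In all 24 probes of 21 genes passed the trend in limma, 13 higher and 11 lower, at adjusted p from 0.000653 for Moxd1 to 0.0476, and 2 of the probes carried no gene name. Slopes do not show even steps: at 0.1X, 1X and 3X Slc7a3 differed from water by 0.86, 0.86 and 0.99, Azgp1 by 0.67, 1.01 and 0.95, and Gcnt1 by -0.58, -1.42 and -1.24. The slopes of Moxd1 and Arhgef25 are fitted values, since neither was detected in water. Of the 9 genes with another kept probe, Iyd alone passed on both, and 9 of 10 other probes had the same direction, among them those of Oxct1 (-0.30 per step), Gcnt1 (-0.28), Azgp1 (0.20) and Ndrg2 (0.09). The 10 include both Iyd probes, which were called themselves, so their matching direction adds nothing. The other probes of Slc7a3 (-0.06 per step), Ptges3l (0.00), Cobl (-0.03) and Igdcc4 (0.06) were dim, with mean log2 signals of at most 4.80. Median scaling gave 13 higher and 6 lower, and dose in mg per kg gave 7 probes. With the erythroid list mean as a covariate 14 passed, 13 of them among the 24. With adipocyte and B cell covariates 9 passed, 8 of them among the 24, and 4 passed without the 5 arrays of high clock score, while 52, all 24 among them, passed with the clock score as a covariate. Without single arrays the count was 11 (water 1), 2 (water 2), 5 (water 3 or 4), 11 (PAE 3X 1), 13 (PAE 3X 2) or 8 (PAE 3X 3 or 4). Without any other single array it was 16 to 28. Reep6 and Moxd1 passed in all 24 such fits, Slamf9 in 23, and Iyd in 3 and 5 on its 2 probes.

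Ribosomal protein genes were lower along the dose for 25 of 31 members (median -0.05 per step), glycolytic enzymes for 10 of 11 (-0.05, or -0.00 under median scaling), and cell cycle genes were higher for 9 of 11 (0.08, or 0.02 under median scaling). These lists had adjusted p = 0.101 each and did not pass. Erythroid genes, markers of blood, were higher for 3 of 5 members (median 0.23 per step, and 0.84 in PAE 3X), without passing (adjusted p = 0.510, and 0.466 in PAE 3X). Adjusted over that list alone, Alas2, the first enzyme of heme synthesis in red cells, rose by 0.31 per step (SE 0.10) and by 0.98 in PAE 3X (SE 0.32). Adjusted over the list alone, Mcm6 (0.29), Mcm5 (0.20) and Mcm2 (0.22) rose per step, and 0 passed over all probes. Fry called 0 lists, with 3 at an unadjusted p under 0.05, while camera called 7 with a preset and 0 with an estimated correlation, and 1 list passed without PAE 1X 2 or PAE 3X 4.

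AFFB, the whole beverage, was set against water. Genes of fatty acid oxidation and PPAR targets were higher for 13 of 14 members (median 0.40), and integrin and focal adhesion genes lower for 13 of 19 (median -0.15), both at adjusted p = 0.0746, which did not pass. Other tested lists of connective and immune tissue were lower too without passing in fry. Collagen and stellate genes were lower for 10 of 12 (median -0.21, adjusted p = 0.371). Endothelial genes were lower for 8 of 10 (-0.18, 0.801) and macrophage genes for 10 of 13 (-0.20, 0.706). Of lists too small to be tested, T and NK cell genes averaged 6.33 against 6.24 in water. B and plasma cell genes averaged 6.36 against 6.63. MHC class II genes had a median of -0.53 and adipocyte genes one of -0.42. Adjusted over the list alone, Acot1 rose by 2.06 (SE 0.61), from 5.87 ± 1.07 to 7.93 ± 1.16 (SD, n = 4 each), and it did not pass over all probes. The gene with the smallest p was Kdsr, an enzyme of sphingolipid synthesis, at -0.79 (SE 0.14, adjusted p = 0.0742), lower on all 4 arrays. Unc93b1, a chaperone of endosomal Toll-like receptors, at -0.71, Aplp2 at -0.61, Adh1 at -0.74, Srsf3, a splicing factor, at 0.79, Fancl at 0.61, Liph at 0.59 and Phf21b at 0.58 followed, all at adjusted p = 0.919. Tcf12 and 1 probe of Hdhd2 were detected on all 4 water arrays and on no AFFB array, at least 1.22-fold and 1.21-fold lower, without passing. Other probes differed by -0.62 for Adh1, -0.12 for Hdhd2, -0.25 for Kdsr, 0.34 for Aplp2, 0.07 for Liph and 0.09 for Srsf3.

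For AFFB limma called 0 probes, with 771 at an unadjusted p under 0.05. It called 1 without water 3 or without PAE 3X 3. Fry called 0 lists, with 4 at an unadjusted p under 0.05, while camera called 6 with a preset and 0 with an estimated correlation. Fry called 1 list without water 2, AFFB 3 or PAE 3X 3, 2 without PAE 3X 1 and 1 with the composition covariates.

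The mean of the 4 berry groups, 3 of them extract, was set against water. Reep6 rose 2.82-fold (SE 0.25 log2 units), Slc7a3 by 0.82 log2 units (SE 0.14) and Azgp1 by 0.80 (SE 0.14). Cobl fell by 0.86 (SE 0.15) and Kdsr fell by 0.58 (SE 0.11), with n = 16 against 4 arrays. In AFFB alone Reep6 differed by 0.84, Slc7a3 by 0.56, Azgp1 by 0.56, Cobl by -0.63 and Kdsr by -0.79, and none passed, so a change common to beverage and extract was not shown. Kdsr was lower in sitagliptin too, so its fall was not shown to be particular to the berry groups. In sitagliptin Reep6 differed by 0.22, Slc7a3 by -0.11, Azgp1 by 0.01 and Cobl by -0.05. In limma the first 4 had adjusted p = 0.0330 and Kdsr 0.0432, and 795 probes had an unadjusted p under 0.05. Gper1 at -0.81 (adjusted p = 0.0506), Rprm at -1.09, Adh1 at -0.76 and Gcnt1 at -0.92 did not pass, nor did Moxd1, which was not detected in water or AFFB. Other probes differed by -0.26 for Kdsr (adjusted p = 0.902), -0.63 for Adh1, -0.77 for Gcnt1, -0.16 for Slc7a3, 0.42 for Azgp1 and -0.04 for Cobl.

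This count rested on single arrays and on the processing. It was 0 without any 1 of the 4 water arrays, AFFB 4, PAE 1X 1, PAE 1X 3, PAE 3X 1 or PAE 3X 4, 1 without PAE 0.1X 1, 2 without AFFB 1 or PAE 0.1X 3 and 3 without AFFB 2 or PAE 0.1X 4. It was also 0 with the composition covariates, the replicate block, no background correction or no filter. Genes of fatty acid oxidation and PPAR targets were higher for 14 of 14 members (median 0.20), and glycolytic enzymes lower for 10 of 11 (median -0.16, or -0.08 under median scaling), both at adjusted p = 0.153. The fatty acid oxidation median was 0.40 in AFFB and 0.42 in PAE 0.1X but 0.01 in PAE 1X and 0.10 in PAE 3X, so the berry mean does not show a difference common to the 4 groups. Fry called 0 lists, with 4 at an unadjusted p under 0.05, while camera called 5 with a preset and 0 with an estimated correlation, and glycolysis passed without PAE 0.1X 2.

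AFFB and PAE 1X had close anthocyanin doses, 8.4 and 9.0 mg per kg per day, which sets the whole beverage against its extract. Smim24 was 1.94 log2 units higher in AFFB (SE 0.27), at 8.51 ± 0.52 against 6.57 ± 0.28 (SD, n = 4 each) and with all 4 AFFB arrays above the PAE 1X mean. Its 95% interval ran from 1.39 to 2.49. Lamb3 at -0.93 (SE 0.17, adjusted p = 0.0894), Mib1, a ubiquitin ligase of Notch signalling, at 0.63 and Scn4b, a sodium channel subunit, at 1.15 did not pass. The serotonin transporter Slc6a4 at -0.78, Fxyd3, a regulator of the sodium pump, at 0.84, Slc12a8 at -0.77, Slc25a35 at -1.19, Krt71 at -0.76 and Ptges3l at -0.70 did not pass either. Other probes differed by 0.01 for Scn4b, -0.33 for Slc6a4 and -0.46 for Ptges3l.

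Smim24 had adjusted p = 0.00222 in limma, and 676 probes had an unadjusted p under 0.05. It passed in all 24 fits that left out 1 array and not when only these 2 groups were fitted, and the count was 2 without AFFB 1 and 3 without AFFB 2, AFFB 3 or PAE 1X 1. Genes of oxidative phosphorylation were higher in AFFB for 28 of 33 members (median 0.14, or 0.08 under median scaling) and those of fatty acid oxidation for 13 of 14 (median 0.32), both at adjusted p = 0.152. Adjusted over the list alone, Hadhb (0.71), Acot1 (2.12) and Ehhadh, a peroxisomal enzyme of fatty acid oxidation (0.69), were higher, and 0 passed over all probes. MHC class II genes were lower for 7 of 7 members (median -0.59, adjusted p = 0.336), among them H2-Aa at -0.75 (SE 0.26). Fry called 0 lists, with 3 at an unadjusted p under 0.05, while camera called 5 with a preset and 0 with an estimated correlation. Fry called 1 list without AFFB 2 and 3 without the 3 arrays farthest on the first principal component.

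Sitagliptin, the reference drug, was set against water. Dpp4, which encodes its target enzyme, differed by -0.20 (SE 0.19), and the incretin and DPP family list had 4 of 6 members higher (median 0.02, or 0.10 under median scaling, adjusted p = 0.977). The genes with the smallest p were Amdhd2, an enzyme of amino sugar breakdown, at 0.78 (SE 0.17), Kdsr at -0.60, Krt71 at 0.66, Coq10b at -0.76, Osbpl8 at 0.48, Ydjc at 0.64, Mapre2 at -0.51, Liph at 0.55 and Hdhd2 at -0.48. Abca17, not detected in water, was at least 1.09-fold higher. None passed, at adjusted p = 1.00 for every one of them, and other probes differed by -0.39 for Coq10b, 0.41 for Liph, -0.04 for Amdhd2, 0.03 for Kdsr, 0.04 for Ydjc, -0.04 for Mapre2 and 0.08 for Hdhd2. Heat shock genes were lower for 9 of 9 members (median -0.38, adjusted p = 0.967).

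For sitagliptin limma called 0 probes, with 420 at an unadjusted p under 0.05, and 0 in each of the 24 fits that left out 1 array. Fry called 0 lists, with 1 at an unadjusted p under 0.05, and camera called 1 with a preset and 0 with an estimated correlation.

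The F test over all 5 treatments asked which genes differed in any group. Smim24 averaged 7.91 ± 0.36 in water, 8.51 ± 0.52 in AFFB, 8.53 ± 0.51 in sitagliptin and 7.46 ± 0.17, 6.57 ± 0.28 and 7.05 ± 0.51 along the extract doses (SD, n = 4 each). Gde1, a glycerophosphodiester phosphodiesterase, averaged 6.03 ± 0.21 in water, 5.34 ± 0.20 in PAE 3X and 6.54 ± 0.20 in sitagliptin. Fxyd3 averaged 7.48 ± 0.36 in water, 6.88 ± 0.28 in PAE 1X and 7.89 ± 0.19 in sitagliptin. Gper1 averaged 5.64 ± 0.22 in water and 4.69 ± 0.25 in PAE 3X, and Acot1 was highest in PAE 0.1X. Moxd1, Ptges3l, Reep6, Slc7a3, Lamb3, Azgp1, Slamf9, Cobl, Gcnt1 and both probes of Iyd changed as well. These 16 probes of 15 genes passed in limma at adjusted p from 0.00205, with 661 probes at an unadjusted p under 0.05, and 1 passed without the 5 arrays of high clock score. With the clock score as a covariate 35 passed, all 16 among them.

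A panel of 20 genes was followed in every comparison, and 14 had a kept probe. None of them passed in any comparison (smallest adjusted p = 0.782). The hormone genes varied between arrays: in PAE 3X the insulin gene Ins2 differed by -0.67 (SE 0.66), the glucagon gene Gcg by -0.76 (SE 0.83), the somatostatin gene Sst by -0.65 (SE 0.74) and the amylin gene Iapp by -0.29 (SE 0.49). The brighter Dpp4 probe was detected on 3 of 4 water arrays and on no AFFB array, at least 1.23-fold lower, while its dimmer probe differed by 0.12, both at adjusted p = 0.919. Ilk, a kinase of focal adhesions, differed by -0.27 (SE 0.12) in the berry mean, at adjusted p = 0.902. The pancreatitis-associated Reg3b lay between 0.63 and 1.68 above water in the 5 treated groups (SE 1.10) on its brighter probe, and the fat cell hormone Adipoq between -0.85 and -0.20 (SE 0.66). The chaperone Hspa5 lay between -0.02 and 0.37 (SE 0.36) on a dim probe, with group means from 5.16 to 5.55. How well that probe reads the gene was not tested. The digestive enzymes Cpa1 and Prss2, the islet factor Pdx1, the collagen gene Col1a1 and the acinar protein Reg1 all lay between -0.15 and 0.14 in the treated groups. Col1a1 and Adipoq were detected on 1 or 2 of 4 arrays in every group, Iapp on 2 or 3 and Hspa5 on 2 in PAE 1X. Their differences thus rest in part on background. Cpa1 averaged 13.71 to 13.91, near the top of the signal range, where saturation was not tested. Amy2b, Cd79a, Gipr, Glp1r, Ins1 and Nqo1 had no kept probe and are not reported.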

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

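The tests of other groupings for AFFB and for the dose trend, the tally of groupings by the arrays far out on the first principal component, the tests on the trend slopes and the tests on the fatty acid oxidation list were chosen after the result was seen. Within each group of 4 arrays, a value was singled out where its gap to the nearest other array took up an unusually large part of the group's range. This was done for 204 groups of values, about 1 in 20 of which would be singled out by chance, and 10 were.

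Slamf9, an immune cell surface receptor, was singled out in PAE 1X 2 (6.958, nearest array 5.76) and in sitagliptin 3 (5.632, nearest 4.705). Arhgef25 stood apart in sitagliptin 3 (5.443, nearest 4.474). Gcnt1, which branches O-glycans, stood apart in PAE 1X 4 (6.336, nearest 5.477), and Fxyd3, a regulator of the sodium pump, in PAE 0.1X 1 (7.059, nearest 7.386). Lamb3, a laminin chain, was high in water 1 (6.048, nearest 5.719), and the brighter Iyd probe in AFFB 2 (9.433, nearest 8.997). Of the array measures, the median correlation of PAE 1X 2 with the other arrays was 0.9321 (nearest 0.9732). The first principal component score of sitagliptin 3 was 33.66 (nearest -8.932), and the clock score of water 4 was 3.831 (nearest -0.3355).

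Reep6, Moxd1, Lpl and the other genes called along the extract dose were tested against 4 technical explanations. With the clock score as a covariate the median of new over old slopes was 1.024, with 24 of 24 probes still called. Without the 5 arrays of high clock score it was 1.052 with 3 of 24, and with fewer arrays standard errors were 1.266 times as large. The kept slopes argue against collection time as the whole cause. A part is left open, since few probes stayed called without these arrays and 2 of them were PAE 3X. Without the 3 arrays far out on the first principal component the ratio was 0.9858, with 23 of 24 still called. With the erythroid list mean as a covariate, for blood, it was 1.045, with 13 of 24 and standard errors 1.095 times as large. These ratios argue against either as the whole cause of the slopes, and a part played by blood is left open. With adipocyte and B cell list means as covariates the ratio was 0.9574, and 8 of 24 were still called, with standard errors 1.111 times as large. The adipocyte list includes Lpl, itself 1 of the 24, so this covariate is not independent of the slopes tested. A part played by adipose or lymphoid tissue therefore cannot be told apart from the dose, and an effect of the dose on these genes may stand beside it as a hypothesis.

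Acot1, Angptl4 and the other fatty acid oxidation genes had a mean change of 0.5949 (95% interval 0.27 to 0.9197) in PAE 0.1X. The adipocyte list changed by -0.1453, with an upper 95% bound of 0.3712, below that mean, so it gave no sign of more adipose tissue. That bound lies above 0.27, and the difference between the 2 lists was not tested, so adipose tissue is not excluded as a source. With adipocyte and B cell list means as covariates the fatty acid oxidation list missed its call in fry (adjusted p = 0.0517). Leaving out any 1 array of PAE 0.1X or water kept at least 0.9077 of the mean change, so no single array carried its size, although the call was lost without several of them. With the clock score as a covariate 0.8886 of the change was kept (0.5286, 95% interval 0.2072 to 0.85), an interval too wide to exclude collection time. An effect of the treatment may explain the rest, but the list's median was 0.01 in PAE 1X and 0.10 in PAE 3X, the higher doses, and fasting state, which was not given in the sources used here, was not tested.

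Dbp and other clock genes were high in water 4, PAE 1X 4, PAE 3X 2, PAE 3X 3 and sitagliptin 4. Another 17 genes known to cycle, none of them in the clock list, had a median absolute t of 1.823 against the clock score, at percentile 98.4 of 10000 random lists of equal brightness. Collection at another time of day is a candidate explanation that this percentile goes with. An effect of array quality stays open at that percentile, since its exclusion needed a higher one, and no biological explanation from the treatments was tested.

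Reep6, Moxd1 and the other 3X genes came from a grouping that stood apart from the others tried. Of 35 groupings of the PAE 3X and water arrays, 1 gave 7 probes or more, the real one, and the highest other gave 0. For the trend 1 of 100 groupings gave 24 or more, again the real one, with 7 as the highest other. Both shares are the smallest that these numbers of groupings allow, and they were not adjusted over the comparisons. They argue against chance and do not exclude it. For the berry mean 4 of 100 drawn groupings gave 5 or more (highest other 537), and for the F test 3 of 100 gave 16 or more (highest other 906), shares too near the threshold for 100 draws to exclude chance. For the berry mean 16 other groupings put 2 of the 3 arrays far out on the first principal component into 1 group, and 3 of them gave as many calls. Of the 83 that, like the real grouping, kept these arrays apart, 0 did, with 2 calls as the highest. For the F test, 1 of 26 with 2 of these arrays together and the 1 with all 3 together gave as many. Of the 72 with them apart 0 did, with 2 calls as the highest. A structure of the samples other than treatment may thus yield many calls, although the median of the groupings with 2 together was 0. The real groups hold no 2 of these arrays together, which argues against their placement as the source of the real counts.

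Reep6 in PAE 1X and Smim24 in AFFB against PAE 1X were the 1 call of their comparisons, and 2 of 35 groupings each gave as many (highest other 1), so chance was not excluded. The fatty acid oxidation call in PAE 0.1X was matched by 4 of 35 (highest other 1), and chance was not excluded. Where 0 was called, every grouping gave as many or more by construction, so these shares say nothing about chance. For probes that was 35 of 35 in AFFB (highest other 0), PAE 0.1X (1) and sitagliptin (0). For lists it was 35 of 35 in AFFB (0), PAE 1X (5), PAE 3X (1), sitagliptin (0) and AFFB against PAE 1X (1), and 100 of 100 in the berry mean (3) and the trend (2).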

How the results depend on the processing

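The tests without the 3 arrays far out on the first principal component or without the 5 of high clock score, with the clock score or the erythroid list mean as a covariate, and on the fatty acid oxidation list without Acot1 and Angptl4 were chosen after the result was seen. No named gene that passed changed direction in any alternative run, and the deposited log2 values gave the same counts. Of 36 named calls, 4 (Moxd1 in PAE 3X and the trend, Reep6 in the trend, Smim24) passed in every fit without 1 array. Probe counts moved as follows. With normexp and an offset of 50, PAE 1X gave 2, PAE 3X 12 and the berry mean 2. Without background correction they gave 0, 12 and 0, and with median scaling 2, 12 and 2. Without a filter, PAE 1X gave 0, PAE 3X 1, the berry mean 0, AFFB against PAE 1X 2, the trend 10 and the F test 6, with more probes to adjust for. With probes detected on all 24 arrays, PAE 1X gave 3, the berry mean 3, AFFB against PAE 1X 2 and the F test 10. With trended robust variances PAE 1X gave 3 and PAE 3X 11. With array weights PAE 1X gave 14, PAE 3X 33, the berry mean 11, AFFB against PAE 1X 2, the trend 67 and the F test 26. With only the groups compared, with fewer arrays for the spread, PAE 1X gave 0, the berry mean 2, AFFB against PAE 1X 0 and the trend 12. With 1 probe per gene PAE 1X gave 4, PAE 3X 15 and AFFB against PAE 1X 2. With composition covariates PAE 3X gave 2, the berry mean 0 and the trend 9, and doses in mg per kg gave 7 for the trend. Without the 3 arrays, PAE 1X gave 0, PAE 3X 19, AFFB against PAE 1X 3 and the trend 39. Without the 5 arrays, PAE 1X (Reep6 lost) and the berry mean (all 5 lost) each gave 1 other probe, a lower one, and PAE 3X gave 0, AFFB against PAE 1X 2, the trend 4 and the F test 1. With the clock covariate AFFB gave 1, PAE 1X 8, PAE 3X 25, the trend 52 and the F test 35, and with the erythroid covariate PAE 1X gave 3, the berry mean 3 and the trend 14.

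List counts moved as follows. PAE 0.1X gave 0 with median scaling, no filter, the replicate block, only the groups compared, composition covariates, fry in either direction, the clock covariate, without the 5 arrays and without Acot1 and Angptl4. No filter gave 1 for PAE 3X, the berry mean and the trend, and probes detected on all 24 arrays gave 1 for PAE 3X and the berry mean. Array weights gave 1 for PAE 1X, 1 for AFFB against PAE 1X and 2 for the trend, and composition covariates 1 for AFFB. Without the 3 arrays PAE 1X gave 1, AFFB against PAE 1X 3 and the trend 1. Camera with a preset correlation gave 6 for AFFB, 2 for PAE 1X, 5 for PAE 3X, 1 for sitagliptin, 5 for the berry mean, 5 for AFFB against PAE 1X and 7 for the trend. A larger offset or no background correction shrinks dim genes by construction: the fatty acid oxidation median in PAE 0.1X went from 0.42 to 0.25 and 0.20. Beyond fewer arrays, more probes or a larger offset, the cause was not tested.

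Without 1 array at a time, probe counts ran from 0 to 1 for AFFB, 0 to 1 for PAE 0.1X, 0 to 8 for PAE 1X, 1 to 15 for PAE 3X, 0 to 0 for sitagliptin, 0 to 7 for the berry mean, 1 to 3 for AFFB against PAE 1X, 2 to 28 for the trend and 12 to 21 for the F test. List counts ran from 0 to 2 for AFFB, 0 to 1 for PAE 0.1X, PAE 3X, the berry mean, AFFB against PAE 1X and the trend, and 0 to 0 for PAE 1X and sitagliptin. The replicate number as a block gave 4 probes in PAE 1X, 0 in the berry mean and 0 lists in PAE 0.1X, and moved no other count by more than 1.5 times. The 60 same-numbered pairs correlated from -0.55 to 0.63 (median 0.03), and 9 of 24 arrays correlated best with their own number. Those correlations, taken after normalization, gave no clear pairing. Before normalization, median signals ran from 81.35 to 85.84 on arrays numbered 1 and from 88.43 to 98.74 on those numbered 2. They ran from 86.38 to 92.14 on number 3 and from 83.15 to 88.07 on number 4. A batch that follows the numbers is thus left open. The bead chip as a block was not run, since the chip of each array is not given in the sources used here. Signal over background limits the dim genes: Moxd1, Arhgef25 and the second Acot1 probe were undetected in water, so their folds over water have only a lower bound and their slopes rest in part on background.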

Other observations

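The list members named here were chosen after the result was seen, and the tests on them were not. Mcm4, Mcm6, Mcm5 and Mcm2, subunits of the helicase that licenses replication, were higher in PAE 3X by 0.51, 0.98, 0.62 and 0.59 log2 units, with Mcm6 and Mcm5 passing over their list alone. In the same group the erythroid genes, markers of blood, had a median of 0.84, with Alas2 at 0.98 passing over its list alone. Unfolded protein response genes were higher in PAE 3X for 19 of 21 members (median 0.24, or 0.41 under median scaling) and along the dose for 19 of 21, and the list passed in neither (adjusted p = 0.466 and 0.384). Ribosomal protein genes were lower in PAE 3X for 25 of 31 (median -0.14, adjusted p = 0.273).

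MHC class II genes, which present antigen on immune cells, were lower in AFFB than in water for 6 of 7 members (median -0.53, adjusted p = 0.371). Adipocyte genes were lower in AFFB for 9 of 11 (median -0.42, adjusted p = 0.371). Heat shock genes were higher in AFFB than in PAE 1X for 9 of 9 (median 0.42, adjusted p = 0.575) and lower in sitagliptin than in water for 9 of 9 (median -0.38), without passing. Acinar digestive enzymes, the main product of the tissue, had a median of -0.05 over 25 genes in AFFB (adjusted p = 0.801), and beta cell genes one of -0.23 over 13 genes in PAE 3X (adjusted p = 0.663). The digestive enzyme list averaged 14 in water, near the top of the log2 signal range, and saturation was not tested.

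Changes from water shared the 4 water arrays, which alone gave a correlation between treatments of 0.482 in simulated data. The measured correlations ran from 0.409 (PAE 0.1X and sitagliptin) to 0.694 (PAE 1X and PAE 3X). All 10 covariances lay within the simulated 95% range of 0.00961 to 0.0501. That range is for the mean over the 10 pairs, and its shuffles could place the deviations of arrays far out on the first principal component in the water group. It therefore cannot judge a single pair, and a shared response was neither shown nor excluded. With separate water arrays for the 2 treatments of a pair, correlations averaged from -0.0385 (PAE 0.1X and sitagliptin) to 0.281 (PAE 1X and PAE 3X). No simulated value was computed for these. Without the 3 arrays far out on the first principal component, AFFB and PAE 1X correlated at 0.353 rather than 0.644. PAE 1X and PAE 3X then correlated at 0.640. No simulated value was computed for this smaller set of arrays.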
